A study of Mus musculus with 7 samples.

How the data were processed

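Expression was measured in mouse plantaris on 7 arrays with 2 dyes, 1 array for each of R3h, R12h, P3h, P6h, P12h, P24h and R4w. Per the labels, the Cy3 channel held the pooled RNA of 8 untrained mice and the Cy5 channel the pooled RNA of 3 to 5 running mice, in this 1 orientation on every array, with no dye swap. The labels give the muscle, the pools, the dyes and the times. The array platform's layout, the scanner, the background correction and the normalization by the authors are not given in the sources used here.

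The deposited values are 1 log2 ratio per probe and array, and no intensities were used here. The log base was settled from the values: the smallest sizes above 0 are the base-2 logarithm of the first double-precision number above 1 (3.20e-16) or a small multiple of it. The scale is therefore known. The median of the deposited values was 0 on each of the 7 arrays, which the many zeros would give by themselves. Without the zeros the medians lay between -0.02 (R12h) and 0.01 (P24h), and those of the tested features between -0.01 (R4w) and 0.03 (P24h). Whether and how the authors centred the arrays stays unknown. The direction stays unknown as well; positive is taken as likely higher in the running pool, from the dyes in the labels and the usual order of red over green. No pair of arrays correlated below 0 (21 pairs, r from 0.228 to 0.789, median 0.615). Pools of 4 mice simulated with no effect against 1 shared control pool of 8 gave r = 0.339, with spread between mice alone and no array error. The covariance between arrays was 0.0294 to 0.158, and the part due to the control pool could not be computed, since no array gives the spread between mice.

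Values within 1e-12 of 0 were taken as spots with no usable ratio. They made up 16.3% of the 16273 probes on R3h, 20.2% on R12h, 16.1% on P3h, 41.7% on P6h, 17.3% on P12h, 30.5% on P24h and 18.7% on R4w, and 1882 probes were at 0 on all 7. The depth behind a ratio is unknown without intensities, so precision rests on the number of arrays.

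Probes were named through the platform annotation, with symbols updated through the gene identifier to current RefSeq names. Of the probes, 13731 had 1 symbol (13687 of them updated), 52 had several and 2490 had none. Probes with the same single symbol were averaged, and the others stayed as unnamed features. Only features measured on all 7 arrays were tested, which left 7982 features, 959 of them from more than 1 probe. The annotation was checked by comparing probes that share a name. Over 1245 pairs with the same symbol the means over the single-run arrays correlated at r = 0.0276, and over 307 pairs with the same accession at r = 0.0691. Counting only names on at most 4 probes, which leaves out repeated control spots, gave 0.00445 over 1092 pairs and 0.00335 over 171 pairs. Moving the names along the table by each of 6001 shifts of up to 3000 rows gave r of at most 0.161 between probes of the same symbol (median -0.00250), and no shift was used. Names are therefore printed as labels of probes. Averaging probes of one name can dilute a change when the names are wrong, so the 3 limma comparisons and the counts per array were also run probe by probe; the gene lists were not.

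Tests used limma (version 3.58.1 in R 4.3.3), lmFit and eBayes on the log2 ratios, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The single-run comparison tested the mean of the 6 single-run arrays against 0. The recovery comparison tested the slope on the sampling order 0 to 4 over R12h, P3h, P6h, P12h and P24h. The trained comparison tested R4w minus the mean of the single-run arrays. Single arrays were described by the number of features with a log2 ratio of at least 1 in size. The 22 gene lists were tested with camera (correlation 0.01), with camera at an estimated correlation and fry beside it. On each array they were set against 10000 random lists of the same size. The designs, lists, alternatives and naming rule were fixed before the data were examined. By that rule the text takes, per test, the 10 largest features in each direction past the threshold (for the single-run arrays only with the same sign on all 6). With fewer than 5 past it in a direction, the 5 with the smallest p are given as values. It also takes the 5 highest and 5 lowest named features of each array, of which the extremes are printed, and up to 4 members of each list with the largest means, of which a selection is printed. Clone, predicted and EST names are passed over. Lists held 3 to 17 measured members.

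The tests were tried on simulated data with the real residual spread of each of the 7982 features and 200 changed ones. The single-run test recovered 99% of 100 features changed by 1 and 99% of 100 changed by 2, with 12 false calls. The recovery test recovered 23% of slopes of 0.25 and 76% of slopes of 0.50 per step, with 0 false calls. The trained test recovered 52% of differences of 1 and 93% of differences of 2, with 10 false calls. The simulated spread was independent between arrays, so these numbers leave out the shared control pool, and the false calls of the single-run test are not an estimate for the real arrays.

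Alternatives were centring each array on its median, scaling the arrays to a common median absolute deviation, every probe by itself, features measured on at least 5 arrays, a robust prior, leaving out the probes whose largest ratio was in the lowest quartile, leaving out each array, other time scales, a later comparison group and a threshold of 1.5-fold. Chosen after seeing the data were the subtraction of the median of the 31 nearest probes in the order of probe numbers (the probe itself left out), leaving out P6h and P24h together, counting every probe with a ratio on an array, and the comparison of each array with the other 6, as deposited and scaled. Whether probe numbers follow the print order is not given in the sources used here. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.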

Results

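RNA from the plantaris, a hindlimb muscle of the mouse, was compared between running and untrained animals on 7 arrays with 2 dyes each. On every array the RNA of 3 to 5 running mice, pooled and labelled with Cy5, was hybridised against the pooled RNA of 8 untrained control mice, labelled with Cy3. The single-run arrays held muscle taken right after 3 h of running (R3h), right after 12 h of running (R12h), and 3, 6, 12 and 24 h after the 12 h run (P3h, P6h, P12h and P24h). The trained array held muscle after 4 weeks of running (R4w). Each condition had 1 array, so no value has a replicate within its condition, and the number of arrays limits the precision throughout. Values are the log2 ratio of the 2 channels. The direction of the ratio is not stated, and a positive ratio is only likely to mean more RNA in the running pool, because those pools carried the red dye and red over green is the usual order. Of 16273 probes, 9023 had a ratio on all 7 arrays and gave 7982 features. Between 16.1% (P3h) and 41.7% (P6h) of the probes were listed at 0 and were taken as having no usable ratio.

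The gene names used here are those that the platform annotation gives each probe, and the values did not bear them out. Probes that the annotation assigns to the same accession did not share their ratios: over 307 such pairs the means over the 6 single-run arrays correlated at r = 0.0691, against -0.0233 over 10000 random pairs. These are correlations across probes, which are not independent replicates. The 24 spots assigned to the Gapdh accession differed among themselves. Their SD was 0.63 on P24h, above the 0.54 of the probes nearest in number, and on the other 6 arrays it was lower than that of those probes, from 0.23 against 0.31 (R4w) to 0.50 against 0.54 (P6h). Among probes annotated to genes of abundant muscle proteins, those of Ckm, Pvalb, Myl2 and Myl3 were listed at 0 on all 7 arrays, while those of Acta1, Myh4 and Actn3 were not. Of all named probes, 9.06% were at 0 on all 7 arrays. These genes were picked by hand and what a 0 stands for is not stated, so no conclusion on the names is drawn from these zeros. Since probes of one name did not agree, each name below is the label of a probe, not an identified transcript, and no function is attached to it. The gene groups below are built from these names, so their counts and tests are those of sets of labels.

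**Figure D1:**
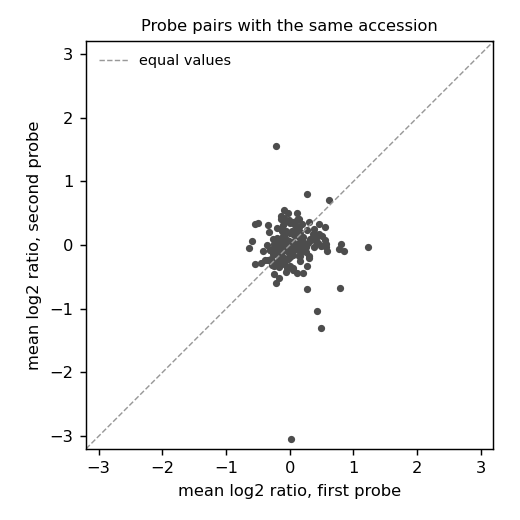
Mean log2 ratio over the 6 single-run arrays of the first (horizontal axis) and second (vertical axis) probe of each pair with the same annotated accession; 171 pairs whose accession is on at most 4 probes are shown, and the dashed line marks equal values. The points form a round cloud with r = 0.00335 and do not follow the line.

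The first comparison asked which features differed from the control pool in their mean over the single-run arrays. Probes of one name were averaged before features were ranked, so strong probes averaged with others of their name are missing below. Probe 2477 (annotated Sike1) had a mean of -3.05, and the other probe of its accession 0.01. Missing as well were probes 11887 (annotated Srp54b, -4.41 on R3h), 14202 (annotated Dlg3, -4.40 on R3h) and 16089 (annotated Sertad1, 3.69 on P3h). The highest means belonged to probe 14989 (annotated Cds2) at 3.80 ± 0.64 and probe 7180 (annotated Tctex1d1) at 3.60 ± 0.60 (SD, n = 6 arrays), both with an adjusted p of 2.11e-05. Probe 2176 (annotated Bckdk) and probe 16184 (annotated Hpca) followed at 2.86 ± 0.66 and 2.86 ± 0.68. Probe 8995 (annotated Usp15) had 2.81 ± 0.40 and stayed high on the trained array, at 2.21. The other 5 of the 10 highest, annotated Higd1b, Casp8, Gna11, Eya1 and Pklr, had means from 2.29 (Pklr) to 2.38 (Higd1b), and adjusted p from 0.000166 (Higd1b) to 0.00332 (Pklr). On P24h the Gna11 probe was at 0.01 and the Casp8 and Eya1 probes at 0.69. The lowest mean belonged to probe 2728 (annotated Lsr), at -3.92 ± 1.57 with an adjusted p of 0.000854. Probe 1308 (annotated Ptprm) had -3.37 ± 1.53 and probe 4740 (annotated Rad54l) -3.21 ± 1.38. When features measured on at least 5 arrays were used, another probe with the Ptprm name joined that feature and its mean was -1.68 (adjusted p 0.0141). The other 7 of the 10 lowest, annotated Epb41l3, Spns1, Tmem179b, Ttc3, Rab2a, Rtn4r and Emilin1, had means from -2.89 (Epb41l3) to -2.50 (Emilin1). All 20 had the same sign on the 6 arrays, which the naming rule required. All 10 low probes were nearer 0 on P3h than on the other single-run arrays, with -0.96 for the Lsr probe and -0.52 for the Ptprm probe.

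In all, 2451 of the 7982 features had a mean that differed from 0 (limma, Benjamini-Hochberg adjusted p under 0.05), 1302 of them positive and 1149 negative. The median size of these means was 0.37, and 72 positive and 63 negative ones reached 1 in size. The sign was the same on all 6 arrays for 1121 of the positive and 964 of the negative features. The 6 arrays are different times rather than replicates of one condition, so the SD holds the time course as well as the error. The control pool is 1 sample in 1 dye orientation, so the test leaves out the control's own spread and any dye effect is part of the mean. Between arrays the ratios correlated at r = 0.228 (P3h and R4w) to 0.789 (R3h and R12h) across probes. Pools of 4 mice drawn with no effect against 1 shared pool of 8 gave r = 0.339 in a simulation, so part of the correlation may come from the shared control. The simulation held the spread between mice alone, with no array error, so the size of that part is not known.

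Gene groups fixed beforehand were followed through the probes that the annotation assigns to them, and the calls within most groups went both ways. All 7982 features likewise held calls of both kinds, 1302 positive and 1149 negative. Of the muscle groups, the fast fibre contractile genes had 3 positive and 0 negative calls among 9 measured members, and the slow fibre contractile genes 3 and 1 among 8. Oxidative phosphorylation and the citric acid cycle had 4 positive and 1 negative among 12, glycolysis and glycogen 3 and 1 among 9, and fatty acid oxidation 2 and 1 among 9. Myogenic regulators and embryonic isoforms had 1 positive and 4 negative among 10, and atrophy and the ubiquitin proteasome 1 and 3 among 12. Of the stress and exercise groups, immediate early genes had 1 positive and 2 negative among 10, genes known to rise after endurance exercise 2 and 2 among 9, heat shock proteins and chaperones 2 and 0 among 9, and metallothionein and oxidative stress 1 and 0 among 4. Glucocorticoid responsive genes had 1 and 1 among 8, the circadian clock 1 and 0 among 8, ribosomal proteins 1 and 2 among 8, and cell cycle and proliferation 2 and 1 among 17. Of the groups for other cell types and the matrix, the extracellular matrix had 5 positive and 3 negative among 15, endothelial markers and angiogenesis 3 and 1 among 10, and cytokines and chemokines 3 and 2 among 14. Macrophage and leukocyte markers had 1 and 4 among 12, adipocyte markers 3 and 0 among 5, erythroid markers 1 and 0 among 4, and Schwann cell and nerve markers 0 and 0 among 3.

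The members with the largest means were the probes annotated C1qa (-2.32 ± 0.72), Mylpf (2.28 ± 1.12), Ndufa5 (1.89 ± 0.54) and Zfp36 (1.21 ± 0.58; SD, n = 6 arrays), each with an adjusted p at or under 0.00199. The probes annotated Tnnc1 and Myh7 had means of 0.90 and 0.85, those annotated Cdkn1a, averaged, -0.94, and those annotated Foxo3 and Myog -0.54 and -0.66. The probes annotated Adipoq and Fabp4 had 0.44 and 0.40, Hspb8 and Bag3 0.50 and 0.47, and Eng 0.49, and of the extracellular matrix list Nid1 and Col6a3 had 0.83 and 0.64 and Col5a2 and Lamb1 -0.78 and -0.51, all past the threshold. Among the 205 list memberships there were 44 positive and 29 negative calls when adjusted over all features, and 48 and 33 over the list alone. All 7982 features together had 1302 positive and 1149 negative calls, so calls were common in and out of the lists. With camera (preset correlation 0.01) 0 of the 22 lists passed an adjusted p of 0.05 in this comparison. The smallest adjusted p was 0.109, for the adipocyte markers (0.847 with an estimated correlation), which was also the 1 list with an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 7 lists passed: adipocyte markers, myogenic regulators, slow fibre contractile genes, heat shock proteins, oxidative phosphorylation, glycolysis, and atrophy. Median, mean and camera direction differed in sign for 5 lists: immediate early genes, genes known to rise after endurance exercise, macrophage and leukocyte markers, glucocorticoid responsive genes and ribosomal proteins.

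The second question was how far each condition stood from the control pool by itself. The number of features with a log2 ratio of at least 1 was 65 on R3h, 96 on R12h, 167 on P3h, 121 on P6h, 83 on P12h, 100 on P24h and 11 on R4w. The number at or below -1 was 97 on R3h, 108 on R12h, 36 on P3h, 139 on P6h, 55 on P12h, 273 on P24h and 48 on R4w. These are counts on single arrays with no test. When the arrays were scaled to a common spread, the counts were 34 and 94 on P24h and 32 and 83 on R4w, and the most negative features were then on R3h (136), followed by P6h (106) and R12h (95). Which direction had more features was not stable on 3 arrays. With every probe that had a ratio, P6h had 181 positive and 169 negative and P12h 119 and 130. The other arrays kept their balance in that count, with 110 and 332 on R3h, 147 and 246 on R12h, 251 and 74 on P3h, 151 and 382 on P24h and 34 and 112 on R4w. With the median of the nearest probes subtracted R12h had 101 and 97 and P6h 128 and 123. The same few probes led most arrays. The Cds2 probe was the highest named feature on R12h (4.11), P3h (4.45), P6h (4.41), P12h (3.66) and P24h (2.88). The highest on R3h was probe 17458 (annotated Pklr) at 4.00, and on R4w the Usp15 probe at 2.21, followed by probe 6429 (annotated Hbegf) at 1.45. The Lsr probe was the lowest named feature on R3h (-4.90), R12h (-4.63), P12h (-3.40), P24h (-5.18) and R4w (-4.71). The lowest named feature was the Ptprm probe on P6h (-4.71) and probe 12174 (annotated Cacnb2) on P3h (-3.15). Some single probes that were averaged with others of their name lay lower. Probe 11887 (annotated Srp54b) was at -4.78 on P6h, and probe 14202 (annotated Dlg3) at -3.48 on P12h. The 5 highest and 5 lowest of all 7 arrays came to 30 different symbols in 70 places.

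**Figure D2:**
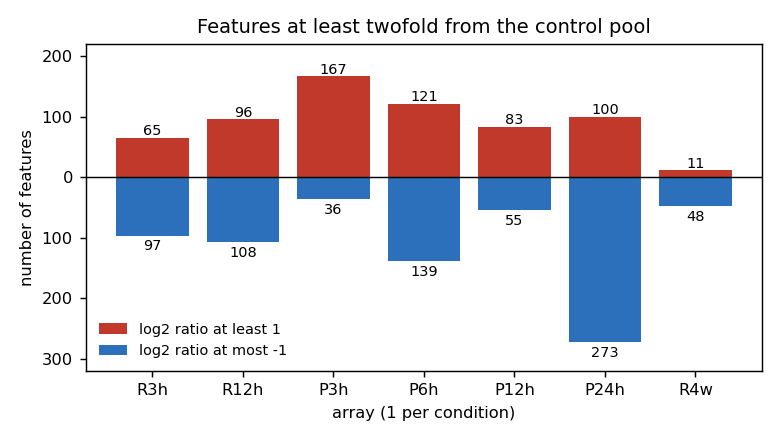
Number of features (vertical axis) with a log2 ratio of at least 1 (red, upwards) or at most -1 (blue, downwards) on each array (horizontal axis, 1 array per condition), as deposited. P3h has the most positive features (167) and the fewest negative ones (36), P24h the most negative ones (273, but 94 against 136 on R3h once the arrays are scaled to a common spread), and R4w the fewest positive ones (11).

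Of 154 pairs of a list and an array, 6 had a list median outside the middle 95% of 10000 random lists of the same size, where 7.7 would fall by chance. The extracellular matrix list had a median of 0.26 on P6h (percentile 99.8) and -0.16 on R4w (percentile 2.02), and the endothelial list 0.29 on P6h (percentile 99.3). The circadian clock list had 0.30 on P3h (percentile 98.2), the cytokine list 0.17 on P12h (percentile 98.0) and the atrophy list -0.26 on P24h (percentile 2.27). With the mean over list members in place of the median, 13 pairs lay outside, and none of these 6 was among them. These percentiles describe single arrays. No intensities were used, so the random lists were not matched on expression.

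The third comparison followed recovery over the 5 arrays from the end of the 12 h run to 24 h later. Only probe 11691 (annotated Tmco1) passed, with a log2 ratio of -2.38 on R12h, -1.64 on P3h, -0.84 on P6h, -0.13 on P12h and 0.16 on P24h. Its slope was 0.66 ± 0.06 per sampling step (SE, n = 5 arrays, limma adjusted p 0.0364). The next upward slopes, none past the threshold, belonged to the probes annotated Zfp93 (0.34 ± 0.05), Immp1l (0.30 ± 0.04), Mapk8ip2 (0.29 ± 0.05) and Lrmda (0.30 ± 0.05), each with an adjusted p of 0.163. The 5 downward slopes with the smallest p, also at 0.163, belonged to the probes annotated Casp8 (-0.66 ± 0.09), Cfdp1 (-0.40 ± 0.06), Efna1 (-0.43 ± 0.06), Pklr (-0.66 ± 0.10) and Eya1 (-0.66 ± 0.10). The Casp8 probe went from 3.08 on R12h to 0.69 on P24h, and the Pklr probe from 3.38 to 1.08. At an unadjusted p under 0.05 there were 966 features. The single call was lost when R12h, P3h, P6h or P12h was left out (adjusted p 0.124 to 0.153), and with log2 hours as the time scale (0.135). With hours as the scale it was lost too, and 1 other probe passed, annotated Gna11, at -0.14 per hour (adjusted p 0.00570). Without P24h, 2 probes passed, the second annotated Wdr61 (0.87 ± 0.06 per step). Camera called 0 of the 22 lists, with 1 at an unadjusted p under 0.05. That was the fast fibre contractile list (median slope -0.10, adjusted p 0.0525, and 0.952 with an estimated correlation), and fry called 0. Adjusted over the list alone there were 1 positive and 2 negative member calls, against 0 and 0 over all features. Median, mean and camera direction differed in sign for 5 lists.

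The last comparison set the trained array against the single-run arrays. Probe 16071 (annotated Slc6a2) was the only feature past the threshold, and it was lower on R4w. Its log2 ratio lay between 1.93 and 2.28 on the single-run arrays (mean 2.05 ± 0.13, SD, n = 6 arrays) and was -0.50 on R4w, a difference of -2.55 ± 0.17 (SE, limma adjusted p 0.000913). The next differences below 0, with no call, were those of the probes annotated Tctex1d1 (-3.15), Arnt (-2.26), Cds2 (-3.12) and Cckbr (-0.95, but -0.44 with features measured on at least 5 arrays), with adjusted p from 0.305 to 0.467. Above 0 and with no call stood the probes annotated Igkv19-93 (1.15), B4galt3 (0.71), Mrpl13 (2.08), Fancd2 (0.97) and Foxo3 (0.64), with adjusted p from 0.467 to 0.564. At an unadjusted p under 0.05 there were 468 features. The trained arm has 1 array, which the test assumes to vary like the others. The call was lost when only P12h and P24h were the comparison (difference -2.50, adjusted p 0.167). It was also lost when features measured on at least 5 arrays were used, where 2 other probes join the Slc6a2 feature (-1.28, adjusted p 0.881). The 1 call there was positive, for the feature annotated Tomm7 (4.73 ± 0.16, adjusted p 0.000258). Camera called 0 of the 22 lists, with 1 at an unadjusted p under 0.05, the adipocyte markers (median difference -0.32, adjusted p 0.414, and 0.833 with an estimated correlation), and fry called 0. Adjusted over the list alone there were 1 positive and 2 negative member calls, against 0 and 0 over all features. Median, mean and camera direction differed in sign for 8 lists.

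A group of probes chosen after the values were seen followed the same course as the Slc6a2 probe. Of 23 probes with a log2 ratio of at least 1 on all 6 single-run arrays, 20 lay below 1 on R4w. Their medians ran from 1.85 on R3h to 2.70 on P3h and P6h and 2.10 on P24h, and were 0.30 on R4w. The probes annotated Cds2, Tctex1d1, Bckdk, Hpca, Sertad1, Ndufa5 and Slc6a2 were among them. A second group, also chosen afterwards, parted P3h from the rest. Of 45 probes at or below -1 on the other 6 arrays, 41 lay above -1 on P3h, among them the probes annotated Lsr, Ptprm, Rad54l, Becn1 and Dlg3. Their median was -0.49 on P3h and between -2.74 (R3h) and -1.94 (P12h) elsewhere.

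**Figure D3:**
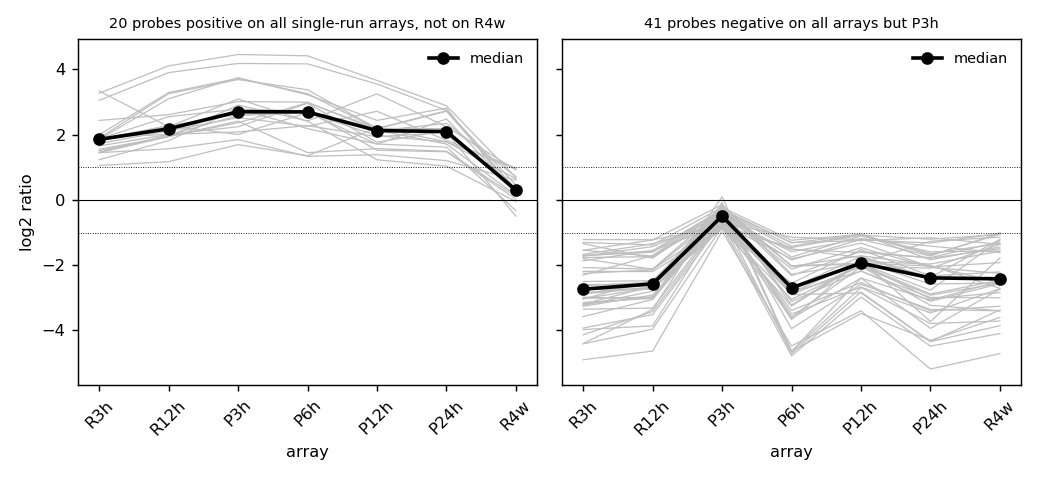
Log2 ratio (vertical axis) on the 7 arrays (horizontal axis) of 20 probes at least 1 on all single-run arrays and below 1 on R4w (left), and of 41 probes at most -1 on all arrays but P3h (right). Grey lines are probes, the black line is their median, and dotted lines mark 1 and -1; the left median drops to 0.30 on R4w and the right one reaches -0.49 on P3h.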

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

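The slope and the difference in this part come from the 2 planned limma comparisons. The tests of explanations were chosen after the data were seen; for those on the order of the arrays and on the order of probe numbers, the bounds were set before their own outcomes were seen.

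The probe annotated Tmco1 (probe 11691) differed between recovery times by the slope test itself, at 0.66 per sampling step from -2.38 on R12h to 0.16 on P24h. The 5 arrays can be put in 60 orders, mirror images counted once, and 2 of them, the real one included, gave at least 1 call; the highest other order gave 1. A count of 1 leaves little room for orders to differ, and 4 of the 60 orders gave at least the real 966 features at an unadjusted p under 0.05, the highest other order 1165. Chance is therefore not excluded.

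The probe annotated Slc6a2 (probe 16071) differed between the trained and the single-run arrays by the test of the difference itself, -2.55 with a log2 ratio of -0.50 on R4w. It belongs to the 23 probes at least 1 on all 6 single-run arrays, of which 20 lay below 1 on R4w. A trend along the order of probe numbers is argued against as the whole cause: after the median of the nearest probes was subtracted, 17 of the 20 still met both sides of the rule. Position on the slide was not tested otherwise. A dye effect fixed to the probe is argued against too, since it would keep the 23 probes near their level on every array, and their median on R4w was 0.35 against 2.23 on the single-run arrays. A difference between single runs and training may account for it, and stays open: R4w is 1 array, so the condition and the array itself cannot be told apart. With any other array as the exception there were 0 such probes, but the choice of probes leaves only 3 that could have been, so this count decides nothing. A second R4w array, or one with the dyes exchanged, would separate them.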

How the results depend on the processing

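No paired analysis was possible because each condition has 1 array. Subtracting the local median, leaving out P6h and P24h together and counting every probe with a ratio were chosen after seeing the data. The single-run total of 2451 stayed within 1.5 times under all alternatives, from 1671 (without R12h) to 3178 of 10498 features (at least 5 arrays); leaving out 1 array gave 1671 to 2936 (without P24h) in all, 879 to 1507 positive and 734 to 1429 negative calls, where the 734 without R12h lies beyond 1.5 times below 1149. Without P6h and P24h the total was 2446, and with the local median subtracted 2595. All 20 named features of that comparison kept their direction and call in 280 of 280 values, though with at least 5 arrays, where other probes join a feature, the means of those annotated Ptprm and Gna11 were -1.68 and 1.56 against -3.37 and 2.33. The recovery call became 0 with scaled arrays, with log2 hours and with the local median subtracted, where the Tmco1 slope was 0.61 per step with scaled arrays and 0.65 with the local median subtracted, against 0.66 (adjusted p 0.0677 and 0.0534), and in another unit 0.58 per log2 hour (0.135), and ranged from 0 to 2 when 1 array was left out: 0 without R12h, P3h, P6h or P12h and 2 without P24h. Fewer arrays lower the power there; otherwise the cause was not tested. The trained call became 2 with scaled arrays and 0 against P12h and P24h alone (fewer arrays), and was 1 whichever array was left out. With features measured on at least 5 arrays, where other probes join it, the Slc6a2 difference was -1.28 against -2.55. The call in that setting was another feature in the other direction, annotated Tomm7 (4.73). No named feature changed sign. Scaling moved the counts at 1 in size to 34 positive and 94 negative on P24h and 32 and 83 on R4w, as it shrinks the wide P24h and stretches the narrow R4w. A 1.5-fold threshold, which is looser by construction, gave 193 positive and 371 negative on R3h, 333 and 443 on R12h, 569 and 205 on P3h, 389 and 532 on P6h, 316 and 175 on P12h, 598 and 807 on P24h and 89 and 189 on R4w. Every probe with a ratio, also more by construction, gave 110 and 332 on R3h, 147 and 246 on R12h, 251 and 74 on P3h, 181 and 169 on P6h, 119 and 130 on P12h, 151 and 382 on P24h and 34 and 112 on R4w. Fry called 7 lists in the single-run comparison against 0 with camera, as it does not compare a list with other genes. Means in place of medians put 13 of 154 list and array pairs outside the middle 95%, against 6. None of the 6 was among the 13. The fast fibre list lay outside on R3h, R12h, P3h, P6h and P12h (percentiles 97.69 to 99.97). The macrophage list did on R3h, R12h, P6h and R4w (0.32 to 2.27). These 2 lists hold the probes annotated Mylpf (mean 2.28) and C1qa (-2.32), and such values move a mean more than a median. Whether these probes account for the difference was not tested. The rest belonged to other lists. No intensities were used, so signal over background sets no limit that can be stated.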

Other observations

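All tests in this part were chosen after the values were seen.

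Each array in turn was compared with the other 6 by limma, which takes the spread from those 6 and assumes that the single array varies like them. The P24h array gave 556 features past an adjusted p of 0.05, 174 higher and 382 lower. P3h gave 7, all higher, R4w 1, lower, and R3h, R12h, P6h and P12h gave 0 each (217, 97, 423 and 56 at an unadjusted p under 0.05). The count for P24h depends on the scale of the arrays: once they were scaled to a common spread it was 24, all lower, with 2 on R4w, 1 on R12h and 0 on the other arrays (422 on R3h, 189 on P3h, 323 on P6h and 179 on P12h at an unadjusted p under 0.05). P24h had the widest interquartile range of log2 ratios as deposited, 0.539 against 0.329 on R4w, and 30.5% of its probes at 0. With 1 array, its condition was not separated from the array itself.

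Of the 45 probes at or below -1 on all arrays but P3h, 41 lay above -1 on P3h. A dye effect fixed to the probe is argued against, since the median of the 45 on P3h was -0.52 against -2.48 on the other arrays. A scale compressed over the whole P3h array is argued against too. Its interquartile range was 0.405, above that of R3h (0.372), P12h (0.352) and R4w (0.329), and it had the most features at or above 1. Neither value covers the low end, where P3h had the fewest features at or below -1 (36). A compression of strongly negative ratios alone on that array therefore stays open. Open as well is a set of RNAs near the control level in the P3h pool and at another level in the other running pools. That level would be lower if positive means more RNA in the running pool, and higher if the ratio runs the other way. Control RNA on that array that differed from the rest, or another effect of the array itself, stays open too. With 1 array for P3h these cannot be told apart. The number of such probes was 0 with any other array as the exception, but only 4 could have been, so this count decides nothing.

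Probes that share a gene name did not share their ratios. Among probes that share a name, 33 had a mean of at least 1 in size (average 1.77). Their partners averaged -0.0584 ± 0.0512 (SE) in the direction of the strong probe. That argues against noise in the partners as what hides a change they share, since such noise would average out. Error of the strong probe itself, repeated on each array, would leave the partners near 0 as well. The test therefore cannot tell such error from names on wrong rows. Whether the names belong to other rows of the value table stays open: the r of 0.0691 between probes of the same accession is the observation itself and gives that explanation no support. The unnamed probes were more often at 0 on all arrays (25.4% of 2490) than the named ones (9.06% of 13783). Having a name was thus related to the zeros, which does not show that a name is on its own row. Among the named, 6.85% of 73 olfactory receptor probes and 4.11% of 73 ribosomal protein probes were at 0 on all arrays. Some probes with different names had nearly the same ratios. Among 212 probes with a ratio over 1.5 in size on some array, 59 pairs differed by a root mean square under 0.2. Both probes were named in 41 of these pairs, such as Sertad1 and Hpca (0.063) or Eya1 and Mylpf (0.066). The name was the same in 0 pairs, but only 1 pair among the 212 probes shared a name. The original print file or the probe sequences would decide whether the names belong to other rows.

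The nearest probes in number order shared part of their ratio on some arrays. The correlation of a probe with the local median of the other probes in its window of 31 was 0.415 on R4w, 0.373 on R3h and 0.287 on R12h. It was 0.139 or less on P3h, P6h, P12h and P24h. These are correlations across probes, which are not independent replicates.

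Among the 5368 probes with a ratio on 1 to 6 arrays, which entered none of the main tests, the largest single values were -6.28 on P3h (probe 16327, annotated Babam1), 6.28 on R12h (probe 17314, annotated Yy1) and -5.53 on P24h (probe 13061, annotated Zfp110). On R4w the probes annotated Tomm7 and Myom1 had 4.77 and 4.76.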
